A study of Mus musculus with 13 samples.

How the data were processed

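Per the labels, the input was 1 file of gene counts per library, 13 files as deposited, each with the same 54532 Ensembl gene identifiers. The submitters' processing notes name HISAT2 2.1.0 and GRCm38. The counting tool, the annotation release and the strand setting are not given in the sources used here. Of the identifiers, 54495 were matched to GENCODE M21 for symbols and coordinates, and 37 had no match. Even numbers made up 49.5 to 65.2 percent of the counts from 1 to 20, and nothing was done about the excess because how reads were counted is not known. Groups were taken from cell type and genotype in the sample labels. Overlapping and antisense genes cannot be told apart without the strand setting, and close paralogs (the Klra family, Hspa1a and Hspa1b) may share reads.

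Genes were tested with edgeR 4.0.16 under R 4.3.3, with TMM scaling, a model with 1 mean per group, and the quasi-likelihood test. A gene was tested if it passed filterByExpr with a minimum count of 10 and a minimum total of 15, which kept 19287. Benjamini-Hochberg adjustment was over all genes tested, and a gene was called at an adjusted p under 0.05. Errors after ± are standard errors for log2 changes and standard deviations between samples for CPM. The 5 comparisons were LrNK labelled CD8KO against LrNK WT, cNK labelled CD8KO against cNK WT, LrNK against cNK within each label, and the difference of the label's effect between the cell types. The comparisons, lists, naming rule and first set of alternatives were fixed before the data were examined.

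Closely agreeing libraries were sought by the chi-square per degree of freedom between 2 libraries over genes with at least 12 counts. The limits (under 4, and 3 times below any other pair of the group) were set after the values were seen. The limit of 4 allowed for a floor of 2, from an assumed 2 counts per read pair. Pairs of cNK libraries gave 8.92 to 18.1. Libraries of an agreeing pair were summed. A library with fewer than 16000 detected genes was put in the set with few detected genes, a limit also chosen after the data were seen.

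Genes were named by rule: for both label comparisons and for LrNK WT against cNK WT, the 12 largest rises and 12 largest falls among called genes with an average log2 CPM of at least 2 and full separation of the groups, and 5 of each for LrNK against cNK labelled CD8KO and for the difference. Predicted genes, pseudogenes and antigen receptor segments were left out. Where fewer than 5 qualified, the 10 genes with the smallest p were named as not passed. List members with the smallest p and 22 marker genes chosen in advance were added. Genes called with cNK fitted alone, genes called by voom, and genes alike in both cell types were added after the data were seen.

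There were 37 lists: liver-resident signature, conventional signature, terminal maturation, immature NK, CD27 and TNF receptor family, cytotoxic granule and death ligand, cytokines and chemokines, activating and costimulatory receptors, inhibitory receptors and checkpoints, Ly49 receptors, transcription factors, IL-2 and IL-15 signalling, IL-12 and IL-18 signalling, TGF-beta signalling, homing, integrins, interferon-stimulated genes, proliferation, immediate-early and stress, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosomal proteins, apoptosis, class I presentation, sex-linked genes, and 11 lists of other cells (T, B, plasma, hepatocyte, Kupffer, neutrophil and monocyte, endothelial, stellate, erythroid, dendritic, mast). All were written from general knowledge of these genes. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and adjusted over the 37 lists, then with an estimated correlation and with fry. A list needed 5 tested genes. List medians marked "with floors" use, for a gene without counts in 1 group, a floor of 3 counts over that group. "Adjusted over the list alone" means Benjamini-Hochberg over the list's own genes.

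Ratios against a group without counts are lower bounds against that floor. Ratios against a group with 1 to 3 counts carry a 95 percent counting interval, which takes each count as independent. Genes within 20 Mb of Cd8a, Cd8a left out, were compared with all others by Fisher's exact test.

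The test was tried on simulated counts with the measured spread and 100 genes changed at each fold. For LrNK by label, the 4-group edgeR fit recovered 45 percent of 2-fold and 87 percent of 4-fold changes with 497 false calls of 18287, the fit of LrNK alone 1 and 36.7 percent with 3 false, voom 11 and 51 percent with 20 false, and DESeq2 66 and 91 percent with 2187 false. For cNK by label, the 4-group fit recovered 40 and 82 percent with 0 false, the fit of cNK alone 100 percent of both with 19 false, and voom 98 and 100 percent with 15 false. LrNK against cNK gave 389 false calls for WT and 151 of 18383 for CD8KO, and the difference 81. When all groups were given 1 spread, false calls were 2 for LrNK and 3 for cNK by label. In the 2 comparisons by label, the only ones so tried, none of 37 lists was falsely called and a raised list was called. Genes were simulated independently of each other, so this trial could not show false list calls that arise from correlated genes.

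Alternatives fixed in advance were RLE scaling, DESeq2 1.42.0, voom with sample quality weights, no filter, a filter of 1 CPM in 3 libraries, only the groups compared, robust quasi-likelihood, replicate block, an adjusted p under 0.01, each library left out in turn, and for lists an estimated correlation and fry. Chosen after the data were seen were all 13 libraries counted separately, detection set as a term, leaving out the 3 libraries with few detected genes, the share of male RNA as a covariate, leaving out both libraries of an agreeing pair, and lists with only the groups compared. Leaving out the few-detected libraries left 1 LrNK sample per label, whose spread was assumed to be that of cNK. Male RNA was the mean CPM of Ddx3y, Eif2s3y, Kdm5d and Uty relative to cNK WT. No reads were realigned, and transcript isoforms, variants and splice forms were not analysed here.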

Results

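Liver-resident NK cells (LrNK) and conventional NK cells (cNK), sorted from mouse liver lymphocytes and labelled either B6 (WT here) or CD8KO, were compared by RNA-seq to ask how their transcripts differ where the label says CD8 is missing. The title of the series concerns maturation of LrNK cells and signalling between CD70 and CD27, so maturation genes and the CD27 family were examined among 37 gene lists fixed before the data were examined. The data were 13 libraries of gene counts: 4 LrNK WT, 3 LrNK labelled CD8KO, 3 cNK WT and 3 cNK labelled CD8KO. In LrNK WT, libraries 2 and 4 agreed closely, though not to within counting error (chi-square per degree of freedom 3.04). So did libraries 2 and 3 of LrNK labelled CD8KO (2.67), whereas all other LrNK pairs gave 196 to 283. Each pair was counted as 1 sample, which left n = 3, 2, 3 and 3. That choice and every check built on detected genes or sex-linked RNA were made after the data were seen. Nothing in the labels says that the samples came from separate animals, so every p-value measures spread between these samples.

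Totals, in units of 1e6 counts, were 30.6 to 43.0 in LrNK WT, 35.9 to 47.7 in LrNK labelled CD8KO, 53.5 to 72.7 in cNK WT and 48.6 to 59.7 in cNK labelled CD8KO. All cNK libraries held 22250 to 22778 detected genes. LrNK libraries fell into a set with few detected genes (WT libraries 1 and 3 with 15159 and 13917, CD8KO library 1 with 15797) and a set with many (19896 to 22921). The biological coefficient of variation was 98.2 percent within the LrNK groups and 9.6 percent within the cNK groups, while the 4-group model assigned 63.2 percent to all of them. Sex-linked RNA was mixed, with Xist at 94.9 and 134 CPM (counts per 1e6 counts of a library) in the LrNK samples labelled CD8KO against at most 1.90 in LrNK WT, and at 0.247, 265 and 815 CPM in cNK labelled CD8KO. A test that shares 1 spread is too strict for cNK and too lenient for LrNK, so for each comparison of 2 groups the calls that remain when only its groups are fitted are given as well.

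**Figure D1:**
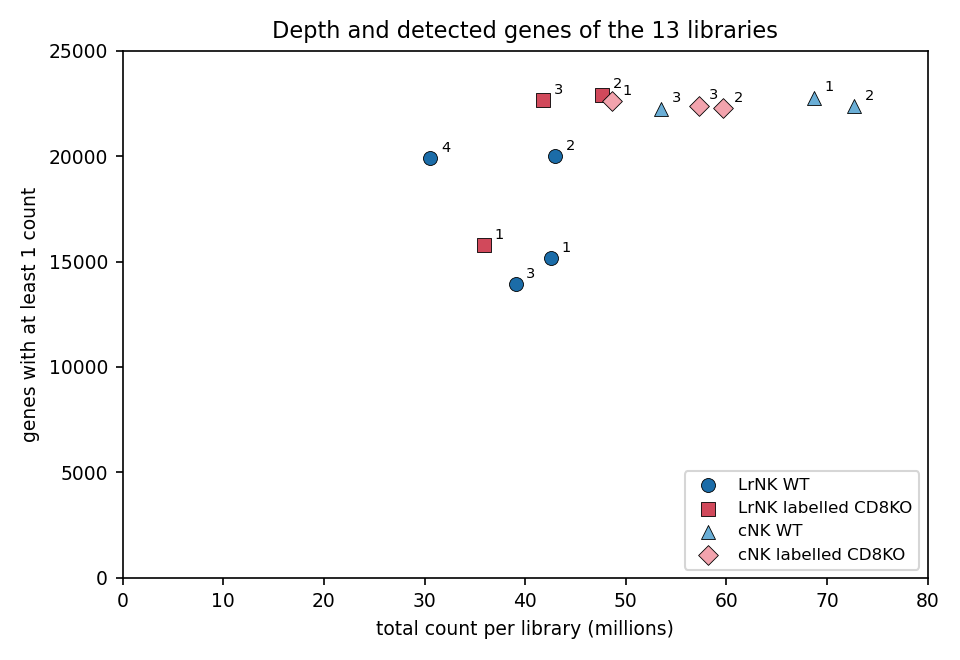
Total count per library (x) against genes with at least 1 count (y), coloured by group, with the replicate number of the label beside each of the 13 libraries. The cNK libraries sit together, while LrNK libraries of both labels split into a set with few and a set with many detected genes.

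The targeted gene was examined first. Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173, GRCm38), which encodes the CD8 alpha chain, was not lost in any library labelled CD8KO. Its CPM values were 40.3, 45.2 and 47.6 in the LrNK libraries labelled CD8KO against 19.6, 19.9, 20.2 and 23.7 in LrNK WT. In cNK they were 85.0, 83.7 and 106 against 0.554, 0.566 and 0.546. Cd8b1, the beta chain gene, had at most 0.602 CPM in any library. The rise of Cd8a passed in LrNK (log2 change 1.11 ± 0.13, edgeR adjusted p = 0.0113) and in cNK (7.36 ± 0.17, edgeR adjusted p = 6.15e-09). An allele that lacks part of a gene can still give counts, and counts per gene do not show which part was read, so the labels are used here as given and not as a measured loss of CD8. Whether the labels were exchanged could not be tested. An exchange would turn the direction of every result by label.

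**Figure D2:**
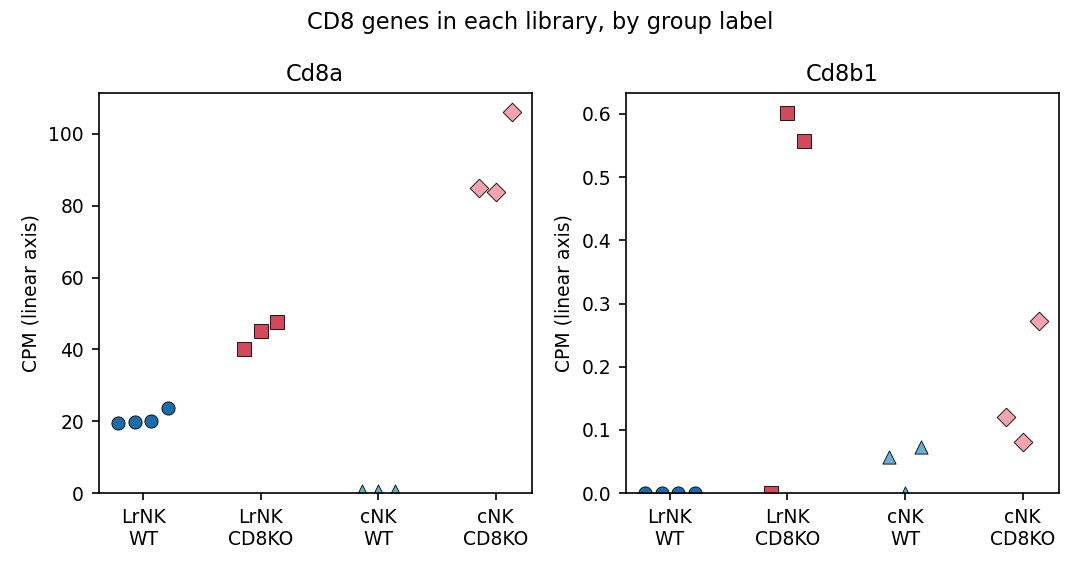
CPM of Cd8a and Cd8b1 in each of the 13 libraries by group, on linear axes. Cd8a is higher in every library labelled CD8KO than in any WT library of the same cell type.

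How did LrNK cells labelled CD8KO differ from LrNK WT? In the 4-group model killing and NK-receptor genes were lower, although no gene, and no list with an estimated correlation, passed with LrNK fitted alone. Granzymes A and B (Gzma, Gzmb), the proteases of cytotoxic granules, fell from 3450 ± 516 to 1042 ± 160 CPM and from 3155 ± 582 to 1181 ± 290 CPM. So did the Ly49 receptors Klra9 and Klra5, the receptor subunit CD94 (Klrd1) and Cd3g, a CD3 chain that LrNK WT carried at 577 CPM. Lists of interferon-stimulated genes and of neutrophil and monocyte genes were higher by camera at its preset correlation and by fry, but not with an estimated correlation (adjusted p = 0.274 and 0.0855). Cd27 was not called, and the lists of maturation genes did not pass camera.

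With edgeR, 104 genes rose and 34 fell of 19287 tested at a Benjamini-Hochberg adjusted p under 0.05. The largest falls were those of the mitochondrial protein gene Apool (−7.18 ± 1.24) and the phosphodiesterase gene Pde1c (−3.32 ± 0.53), and Avil (−1.91), Platr25 (−1.66), Kcnj8 (−1.37) and Sept4 (−1.32) fell as well, all 6 at edgeR adjusted p from 0.0240 to 0.0493. With smaller p-values came the protease Htra3 (−2.87 ± 0.31, edgeR adjusted p = 0.00529), Klra9 (−2.11 ± 0.11, 3.67e-05), Klra5 (−1.98 ± 0.17, 0.00146), Gzma (−1.73 ± 0.17, 0.00290), Cd3g (−1.63 ± 0.15, 0.00146) and Gzmb (−1.42 ± 0.20, 0.0198). Largest among the rises was Elovl7, a fatty-acid elongase gene with 1 count in LrNK WT and 128 in LrNK labelled CD8KO (163.5-fold, 95 percent counting interval 29.34 to 6457). Next was Thbs1, which encodes the matrix protein thrombospondin 1 (3.58 ± 0.32, 7.97 to 95.4 CPM, edgeR adjusted p = 0.00146). The other large rises were Arhgef11 (2.71), Tiam1 (2.51) and Cdc42bpb (2.23), the matrix and scavenger genes Emilin2 (2.24) and Lrp1 (2.12), the protease inhibitor gene Slpi (2.68), the calcium channel gene Trpm2 (2.20), and Asph (2.97), Ndrg1 (2.94) and Soga1 (2.36), all 10 at edgeR adjusted p from 0.0142 to 0.0493. The haem-regulated repressor Bach1 rose from 62.6 to 177 CPM (2.82-fold, edgeR adjusted p = 0.000290).

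Among the 37 lists, 14 passed camera with its preset correlation. Where a list is followed by 2 p-values, the first is camera's adjusted p at that preset and the value after "then" is its adjusted p with an estimated correlation. Cytotoxic granule and death ligand genes were lower (median log2 change −0.39, camera adjusted p = 1.22e-09, and adjusted p = 0.0401 with an estimated correlation, but 0.309 so with LrNK fitted alone). Of those 20 genes 2 fell over all genes, Gzma and Gzmb, while 8 fell and 1 rose adjusted over the list alone. Perforin (Prf1, −0.66) and the death ligand TRAIL (Tnfsf10, −0.44) did not pass (edgeR adjusted p = 0.0982 and 0.344). Activating and costimulatory receptors were lower (median −0.43, camera adjusted p = 3.19e-11, and adjusted p = 0.00702 with an estimated correlation, but 0.173 so with LrNK fitted alone), with 4 of 20 fallen over all genes and 10 adjusted over the list alone, among them Klrd1 (−0.92 ± 0.11, edgeR adjusted p = 0.00761), Klrc2 (−0.74) and Cd7 (−0.80). Ncr1 (−0.45) and Klrb1c (−0.63), which encode NKp46 and NK1.1, did not pass. Ly49 receptors were lower (11 genes, median −0.14, mean −0.35, camera adjusted p = 1.08e-08, and adjusted p = 0.00702 with an estimated correlation, but 0.173 so with LrNK fitted alone), with Klra9, Klra5 and Klra3 (−1.07) fallen over all genes and 4 adjusted over the list alone. Klra sequences are alike, so reads may be shared among them. Inhibitory receptors and checkpoints gave a lower median (−0.31) but a higher mean (0.15), with 3 fallen over all genes (Klri2 −1.20 ± 0.11, Klre1 −0.78, Klrc1 −0.70) and 2 risen and 7 fallen adjusted over the list alone. That list passed as lower (camera adjusted p = 0.000452, but adjusted p = 0.0855 with an estimated correlation).

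Interferon-stimulated genes were higher (median 0.93, camera adjusted p = 1.60e-10, but adjusted p = 0.274 with an estimated correlation). Of 25, 2 rose over all genes, the antiviral genes Oasl1 (1.54 ± 0.27) and Oas3 (1.51 ± 0.28), and 13 adjusted over the list alone. The liver-resident signature was slightly lower (28 genes, median −0.24, none fallen over all genes and 2 adjusted over the list alone, camera adjusted p = 0.000874, but adjusted p = 0.227 with an estimated correlation). Its markers Itga1 (−0.86) and Cxcr6 (−0.68) did not pass. Glycolysis genes were higher (median 0.20, 1 risen over all genes, Pfkfb3 at 0.96, and 5 adjusted over the list alone, camera adjusted p = 0.0293, but adjusted p = 0.422 with an estimated correlation). Small shifts without a single gene passing were lower for oxidative phosphorylation (−0.23, camera adjusted p = 0.000141, but adjusted p = 0.385 with an estimated correlation), ribosomal proteins (−0.22, 1.04e-05, then 0.469) and class I presentation (−0.10, 0.0479, then 0.422). With LrNK fitted alone class I presentation did not pass camera at the preset either (adjusted p = 0.0598).

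Genes of other cells moved in the same libraries. B-cell genes were higher (19 genes, median 3.04, none risen over all genes and 7 adjusted over the list alone, camera adjusted p = 7.01e-08, but adjusted p = 0.227 with an estimated correlation). Neutrophil and monocyte genes were higher as well (16 tested, median 1.59, 1 risen over all genes, Cd14 at 1.64 ± 0.30, and 4 risen and 1 fallen adjusted over the list alone, camera adjusted p = 7.48e-07, but adjusted p = 0.0855 with an estimated correlation). Plasma-cell genes (8 tested, median 1.82, camera adjusted p = 0.00356, but adjusted p = 0.0893 with an estimated correlation) and Kupffer-cell genes (16 tested, median 0.56, 0.0341, then 0.607) followed. The direction of the Kupffer list reversed when library 1 of LrNK labelled CD8KO was left out. Summed CPM of the B-cell list overlapped between labels, at 4733, 1895 and 8014 in LrNK WT and 7904 and 6603 in LrNK labelled CD8KO. Neutrophil and monocyte sums overlapped too (2641, 1342 and 4657 against 9406 and 3171). So did Kupffer sums (829.8, 300.1 and 1050 against 1967 and 981.5), while plasma-cell sums did not (at most 514.5 against at least 587.3).

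The lists that bear on maturation did not pass camera. They were terminal maturation (camera adjusted p = 0.861, 2 fallen over all genes), the immature NK list (0.582, 1 risen and 1 fallen) and the conventional signature (0.240, 4 fallen, with a median of 0.53 although the test pointed lower). Changes in both directions within a list did pass fry's mixed test for the conventional signature (adjusted p = 1.61e-06) and terminal maturation (adjusted p = 0.000793). Cd27 changed by −0.15 (edgeR adjusted p = 0.841), and Cd70, which encodes its ligand, had too few counts to be tested. The CD27 and TNF receptor family list did not pass either (19 tested, median 0.24, camera adjusted p = 0.240). Among single markers, Itgam (1.49, on the terminal maturation list), Tcf7 (0.74), Zeb2 (1.40), S1pr5 (0.93) and Eomes (1.75) did not pass. Neither did Tbx21 (−0.16), Klrg1 (0.16), Il7r (−0.04), Itga2 (−0.56) and Ifng (−0.62). The edgeR adjusted p of these markers ran from 0.0514 to 0.982. Neutrophil and monocyte genes were higher in the same libraries, so which cells gave the Itgam counts is not known. Kit (1.01 ± 0.14) and Itga5 (1.02 ± 0.13) did rise.

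No call was made for cytokines and chemokines (camera adjusted p = 0.162), transcription factors (0.246), IL-2 and IL-15 signalling (0.521), IL-12 and IL-18 signalling (0.861), TGF-beta signalling (0.114), homing receptors (0.240) and integrins (0.546). The same held for proliferation (0.273), immediate-early and stress genes (0.582), cholesterol synthesis (0.135) and apoptosis (0.968). Lists of T cells (0.514), hepatocytes (0.514), endothelial cells (0.0861), stellate cells (0.0861), erythroid cells (0.182), dendritic cells (0.240), mast cells (0.491) and sex-linked genes (0.758) did not pass either. With LrNK fitted alone, endothelial (camera adjusted p = 0.00919), stellate (0.0331) and dendritic-cell lists (0.0240) passed as higher at the preset. With an estimated correlation they did not (0.398, 0.595 and 0.348).

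These calls rest on few samples that vary widely. No gene passed when only the LrNK groups were fitted, where 16 lists passed camera at the preset correlation and 0 with an estimated correlation or by fry. With the replicate number as a block 11 genes were higher and 10 lower. Limma voom with sample quality weights called 12 genes, 11 of them shared with the 138 called here: Htra3, Klra5, Klra9, Cd3g and Gzma lower, and Ifi207, Thbs1, Trib1, Bach1, Tiam1 and Cd14 higher, with Tlr2 (1.69, edgeR adjusted p = 0.0852) called by voom alone. In data simulated with the measured spread, the shared-spread test made 497 false calls with 18287 genes tested. That is more than the 138 calls made here, and voom made 20 false calls there, more than its 12. Both tools used the same samples, so single genes are not established by the count of calls or by the overlap. Within the detection sets, which split the same samples into 2 against 1 and 1 against 1, Gzma changed by −1.77 among libraries with few detected genes and −1.80 among those with many. Separated genes were 16.8 percent of those tested, against 20 percent by chance alone.

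**Figure D3:**
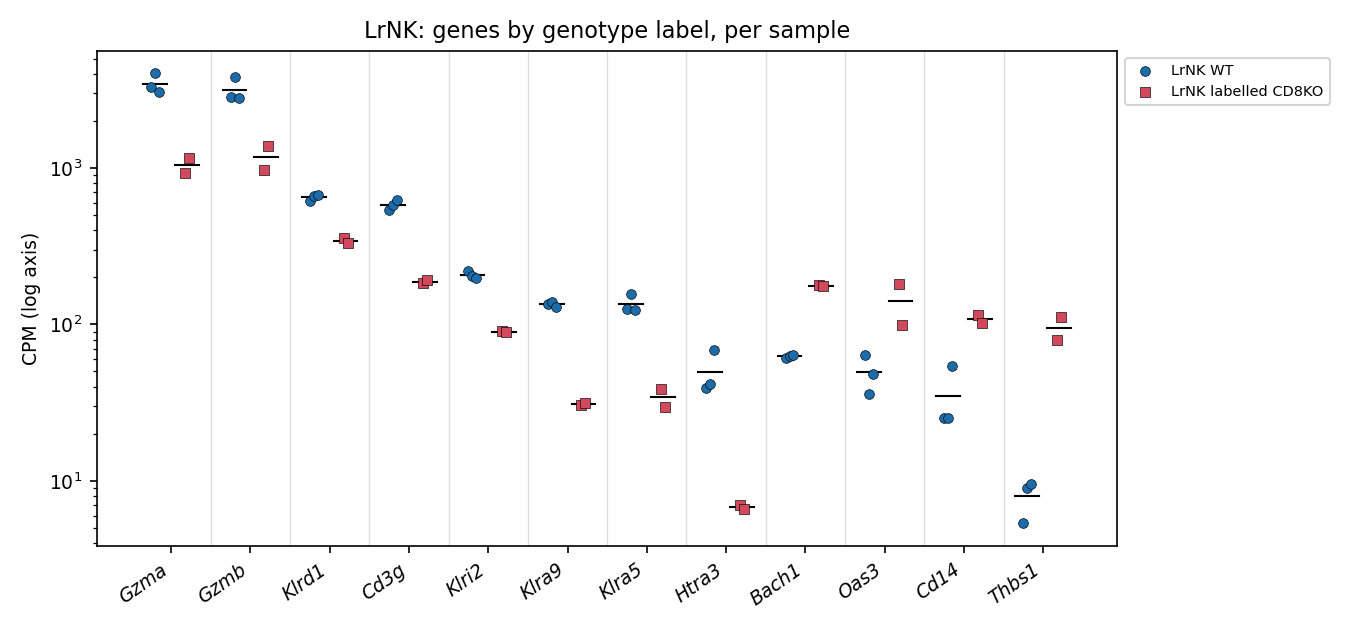
CPM on a log axis for genes that differed by label in LrNK (x), in each of the 3 LrNK WT samples (circles) and 2 LrNK samples labelled CD8KO (squares), with the group mean as a black line. Granzyme and lectin receptor genes are lower and Bach1 and Thbs1 higher in both samples labelled CD8KO.

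What changed in cNK cells labelled CD8KO? Very little at a shared spread: apart from Cd8a no gene passed, and NK markers were level. Cd27 (0.09), Prf1 (−0.05), Gzma (0.13) and Eomes (0.08) all had an edgeR adjusted p of 1. The genes with the smallest p-values included heat-shock genes, the chaperones Hspa1a and Hspa1b, and Klra8, which encodes the activating receptor Ly49H. With cNK fitted alone, heat-shock genes and the chemokines Ccl3 and Ccl4 were lower and Itga1, an integrin that marks tissue residence, was higher.

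The 4-group model called 1 gene higher and 0 lower, with 136 genes at an unadjusted p under 0.05. After Cd8a came Apool, with no count in the 3 cNK samples labelled CD8KO and thus at least 599.8-fold lower against a floor of 3 counts (edgeR adjusted p = 0.188). Pde1c (−2.54 ± 0.43), Hspa1a (−3.77 ± 0.66), Hspa1b (−3.67 ± 0.65), Klra8 (−0.71 ± 0.13), Rab4a (2.44 ± 0.45) and Hsph1 (−1.14 ± 0.21) were at edgeR adjusted p = 0.525, and Dab2 (0.139 against 0 CPM) at 0.599. Thbs1 had 1 count in cNK WT and 21 in cNK labelled CD8KO (24.57-fold, 95 percent counting interval 4.409 to 970.3). DESeq2 called 9 higher and 11 lower on the same model.

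With only the cNK groups in the fit, 83 genes were higher and 135 lower, and voom with sample weights called 193, of which 146 were shared. In simulated data the cNK-only fit recovered 100 percent of 2-fold changes with 19 false calls among 16540 tested genes, where the 4-group fit recovered 40 percent with 0 false. Largest among the rises after Cd8a were the ubiquitin ligase gene Mid1 (3.55 ± 0.17, cNK-only edgeR adjusted p = 1.35e-08), granzyme K (Gzmk, 1.13 ± 0.15), Podnl1 (0.79), Ramp1 (0.77), Itga1 (0.75 ± 0.09, 10.5 to 17.7 CPM), Mgst2 (0.74), Tmem154 (0.70), Spag5 (0.68), Cd3g (0.66 ± 0.11), H1f0 (0.66) and Abcb9 (0.64). The falls were Apool, Hspa1a (−3.79 ± 0.50), Hspa1b (−3.71 ± 0.43), Pde1c (−2.53 ± 0.18), Kctd15 (−1.21 ± 0.11), the co-chaperones and chaperones Hsph1 (−1.14 ± 0.15), Dnaja1 (−0.93 ± 0.14) and Hsp90aa1 (−0.83 ± 0.11), the chemokines Ccl3 (−1.08 ± 0.08, 275 to 131 CPM) and Ccl4 (−0.81 ± 0.07), Cdkn1a (−0.91) and Rell1 (−0.86). Reads of Hspa1a and Hspa1b may be shared, since the 2 sequences are nearly the same.

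**Figure D4:**
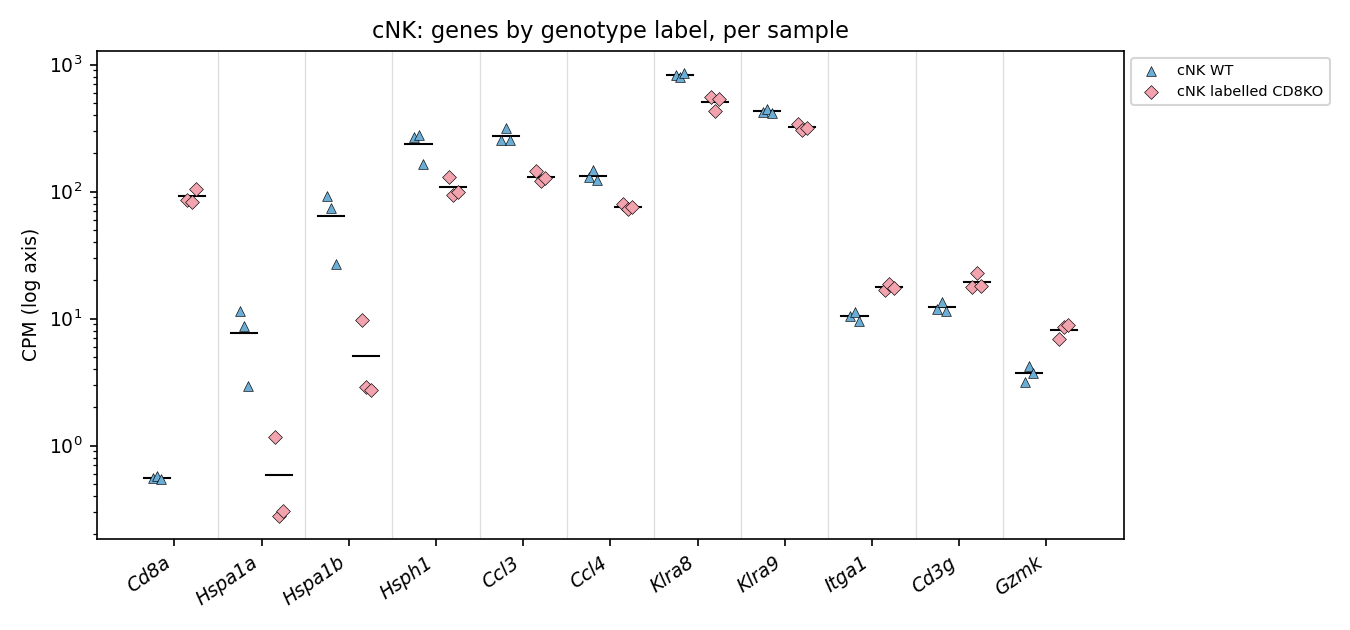
CPM on a log axis for genes that differed by label with cNK fitted alone (x), in each of the 3 cNK WT samples (triangles) and 3 cNK samples labelled CD8KO (diamonds), with the group mean as a black line. Heat-shock genes and chemokines are lower, and Cd8a, Itga1 and Gzmk higher, in all 3 samples labelled CD8KO.

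At the shared spread 11 lists passed camera in cNK, and none did with an estimated correlation or with fry. With cNK fitted alone 10 passed camera and again 0 with an estimated correlation or with fry's directional test. Fry's mixed test passed for most lists in that fit, such as the stress list and the conventional signature (both adjusted p = 0.00261). Immediate-early and stress genes were lower (median −0.28, camera adjusted p = 1.20e-11, but adjusted p = 0.269 with an estimated correlation), with 0 fallen over all genes, 4 adjusted over the list alone and 8 in the cNK-only fit. Ly49 receptors were slightly lower (−0.09, 8.21e-05, then 0.0856), with 2 adjusted over the list alone and 4 in the cNK-only fit. Small rises went with the T-cell list (0.22, 7.68e-06, then 0.134), the liver-resident signature (0.13, 3.48e-05, then 0.134), neutrophil and monocyte genes (0.61, 0.000338, then 0.169), the immature NK list (0.09, 0.00253, then 0.319), dendritic-cell genes (0.13, 0.00499, then 0.134) and class I presentation (0.07, 0.0304, then 0.413). In the same order of values, small falls went with the conventional signature (−0.03, 0.00933, then 0.134) and cytokines and chemokines (−0.15, 0.0119, then 0.591), of which 4 fell in the cNK-only fit. Sex-linked genes passed as lower (0.0259, then 0.205) with a median of −0.93 and a mean of 1.34. With cNK fitted alone camera no longer passed neutrophil and monocyte, dendritic-cell and sex-linked genes (adjusted p from 0.215 to 0.648), and passed proliferation (0.00229) and B-cell genes (0.0153) instead. No single member of the 11 lists passed over all genes at the shared spread.

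Did the label act differently in LrNK and cNK? Granzyme A and a few receptor genes were called. The label's effect on Gzma was lower in LrNK than in cNK (difference −1.86 ± 0.22, edgeR adjusted p = 0.0179), as it was for Klra5 (−2.08 ± 0.22), Klra9 (−1.69 ± 0.14), Klri2 (−1.08), Htra3 (−3.16 ± 0.40) and Cd3g (−2.28 ± 0.19). Bach1 rose in LrNK only (1.48 ± 0.14, edgeR adjusted p = 0.00310). Cd8a rose in both, by less in LrNK (−6.25 ± 0.21, edgeR adjusted p = 4.58e-07). These 8 genes, 1 higher and 7 lower, were the only ones to pass, and the same test made 81 false calls in simulated data, so single genes are not established here either. Gzmb (−1.16) and Itga1 (−1.62) did not pass (edgeR adjusted p = 0.230 and 0.140). Voom with sample weights called 6, sharing 5, but made 30 false calls in simulated data.

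Of the lists, 12 passed camera for the difference, which compares the label's effect between the cell types and not the level of the genes. The effect was lower in LrNK than in cNK for cytotoxic genes (camera adjusted p = 1.75e-08, but adjusted p = 0.0569 with an estimated correlation), activating receptors (3.54e-10, then 0.0198) and Ly49 receptors (5.55e-05, then 0.0429). It was lower too for the liver-resident signature (3.08e-06, then 0.0958), inhibitory receptors (0.000699, then 0.0948, median −0.27 against a mean of 0.23), oxidative phosphorylation (7.87e-05, then 0.378), ribosomal proteins (0.000105, then 0.604), class I presentation (0.00717, then 0.313) and T-cell genes (0.0211, then 0.378, with a mean of 0.003). It was higher for interferon-stimulated genes (8.57e-07, then 0.416), B-cell genes (2.16e-06, then 0.261) and plasma-cell genes (0.00784, then 0.124).

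How did LrNK WT differ from cNK WT? The 2 cell types separated along genes of residence and circulation. LrNK WT carried Itga1 (CD49a), the liver-homing receptor Cxcr6, TRAIL (Tnfsf10) and the residency factor Hobit (Zfp683). Conventional cells carried Eomes, CD49b (Itga2), the egress receptor S1pr5, Klrg1 and Klra8. Granzymes B and C were higher in LrNK, whereas perforin was lower. Tbx21 (T-bet) and Cd27 were not called.

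Here 2300 genes were higher and 2578 lower (1797 and 1617 with only these groups fitted, where 25 lists passed camera, 31 fry and 5 an estimated correlation), and 44.2 percent of genes separated the groups fully against 10 percent by chance. Of the 28 liver-resident genes, 26 rose and 1 fell (median 3.46, camera adjusted p = 9.65e-69, and adjusted p = 0.000117 with an estimated correlation), led by Zfp683 (6.80 ± 0.30), Cxcr6 (6.15 ± 0.29, 266 against 3.74 CPM), Itga1 (4.70 ± 0.21) and Tnfsf10 (3.45 ± 0.20). Of the 28 conventional genes, 24 fell and 1 rose (median −3.41, 5.01e-41, then 0.000117), among them Eomes (−8.02 ± 0.70, 2.39 against 644 CPM), S1pr5 (−5.17 ± 0.32), Klrg1 (−5.32 ± 0.72), Itga2 (−3.77 ± 0.18) and Itgam (−3.05). Terminal maturation genes were lower (13 of 21 fell, 2 rose, median −1.02, 6.32e-07, then 0.00660), with Zeb2 at −1.99. Ly49 receptors fell (8 of 11, 2 rose, median −3.33, 1.27e-14, then 0.000832), with Klra8 at −6.95 ± 0.17 and Klra4 at −9.51 ± 0.74, though Klra5 rose (3.60). Inhibitory receptors rose (12 of 19, 3 fell, median 1.43, 6.61e-06, then 0.0115), with Lag3 at 4.55 and Cd200r1 at 4.78. IL-2 and IL-15 signalling genes rose (8, 1 fell, median 0.47, 2.96e-05, then 0.0115), with the inhibitor gene Cish at 3.76, and so did class I presentation (11, 0 fell, median 0.57, 6.80e-06, then 0.0417), with B2m at 0.72. Gzmb rose (2.32 ± 0.18) and Gzmc (6.81 ± 0.25), while Prf1 (−1.98 ± 0.14) and Gzma (−0.51 ± 0.14) fell. Ncr1 (−0.81), Klrb1c (−0.50) and Tcf7 (−2.10) were lower, and Il7r (1.00) and Ifng (1.64 ± 0.42) higher. Cd27 (−0.43) and Tbx21 (−0.03) were not called (edgeR adjusted p = 0.0925 and 0.967).

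With only these groups fitted, an estimated correlation still passed the liver-resident signature (adjusted p = 0.00452), the conventional signature (0.00537) and Ly49 receptors (0.0167), but not terminal maturation, inhibitory receptors and IL-2 and IL-15 signalling (all 0.0517) or class I presentation (0.0541).

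The list values for LrNK WT against cNK WT that passed at the preset but not with an estimated correlation began with cytokines and chemokines (12 of 18 rose, median 2.56, camera adjusted p = 4.17e-08, but adjusted p = 0.0642 with an estimated correlation), with Xcl1 at 3.23. Immediate-early and stress genes rose (20 of 26, median 2.74, 3.63e-15, then 0.0958), for instance Atf3 (8.03), Dusp1 (4.84) and Fos (3.05). Higher too were cholesterol synthesis (10 rose, median 1.15, 6.00e-08, then 0.0609, though 0.0416 with only these groups fitted), interferon-stimulated genes (12 rose, 0.72, 2.33e-05, then 0.260), glycolysis (9 rose, 1 fell, 0.48, 0.000274, then 0.104), oxidative phosphorylation (8 rose, 0.28, 0.00120, then 0.259) and ribosomal proteins (12 rose, 0.34, 2.87e-05, then 0.334). The same held for the CD27 and TNF receptor family (9 rose, 1 fell, 0.48, 0.0113, then 0.0958), with Ltb at 1.81, the immature NK list (12 rose, 7 fell, 0.94, 0.00387, then 0.197) and apoptosis genes (9 rose, 3 fell, 0.36, 0.0427, then 0.104, and not at the preset with only these groups fitted, 0.0756). Integrins were lower (5 rose, 11 fell, −0.67, 0.0121, then 0.145), with Itga4 at −3.61. Cytotoxic genes passed as higher with a median of −0.08 and a mean of 0.18 (4 rose, 3 fell, 0.0353, then 0.259), and transcription factors with a median of −0.03 and a mean of 0.35 (13 rose, 9 fell, 0.0356, then 0.397). Activating receptors (0.736), IL-12 and IL-18 signalling (0.177), TGF-beta signalling (0.156), homing receptors (0.156), proliferation (0.544) and sex-linked genes (0.936) did not pass camera, although Il18r1 (−2.98) and Klrc2 (−1.49) fell as single genes.

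Lists of genes typical of other liver cells were higher in the LrNK libraries. Hepatocyte genes rose (18 of 28, median 6.31 with floors, camera adjusted p = 5.30e-13, and adjusted p = 0.0124 with an estimated correlation), as did neutrophil and monocyte genes (9, median 3.91 with floors, 7.31e-11, then 0.0115), dendritic-cell genes (10, median 3.93 with floors, 2.22e-06, then 0.0115) and T-cell genes (11 of 17, 2 fell, median 2.09, 5.30e-13, then 0.00726). Endothelial (8, median 3.87 with floors, 0.000564, then 0.0936), erythroid (6, median 5.84, 0.00323, then 0.225) and B-cell genes (6, 1 fell, median 0.04, 0.0495, then 0.397) passed at the preset but not with an estimated correlation. Plasma cells (0.156), Kupffer cells (0.496), stellate cells (0.201) and mast cells (0.544) did not pass. With only these groups fitted, the estimated-correlation value stayed under 0.05 for T-cell genes (adjusted p = 0.0167) but not for hepatocyte (0.0990), neutrophil and monocyte or dendritic-cell genes (both 0.0541), and camera at the preset no longer passed B-cell genes (0.0971). Examples were Lyz2 (7.09, 1972 against 14.4 CPM), Cd74 (5.46, 2189 against 49.6 CPM) and H2-Ab1 (6.27). Cd3g, on the T-cell list, rose as well (5.55 ± 0.15).

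The largest changes between LrNK WT and cNK WT were against groups with few or no counts. Against a floor of 3 counts over the cNK WT samples, which had no count, LrNK WT was at least 7099-fold higher for the chemokine gene Cxcl2, 1023-fold for F13a1, 983.6-fold for F10, 806.1-fold for Bhmt, 782.9-fold for Ccl2, 742.9-fold for Clec4f, 703.3-fold for Ptgs2, 491.2-fold for Arhgef37 and 464.4-fold for Skint3. Albumin (Alb) had few counts in cNK WT (5008-fold, 95 percent counting interval 898.9 to 197800), and Mmp9 (11.69 ± 0.42) and Ace (11.43 ± 0.73) came next. With no count in LrNK WT, cNK WT was at least 901.2-fold higher for Khdc1c, 802-fold for Rhpn1, 776.5-fold for Clip4, 495.5-fold for Dpysl5, 449.7-fold for Ccr3 and 411.5-fold for Clip3, and Elovl7 was 5105-fold higher (95 percent counting interval 916.2 to 201600). Klhl30 (−10.83 ± 0.63), Gfra2 (−9.61 ± 1.26), the mast-cell protease gene Cma1 (−9.55 ± 0.92) and Phactr3 (−8.75 ± 1.20) completed the falls. Floors and intervals cover counting error only and take each count as independent. If both reads of a pair were counted, these intervals are too narrow.

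**Figure D5:**
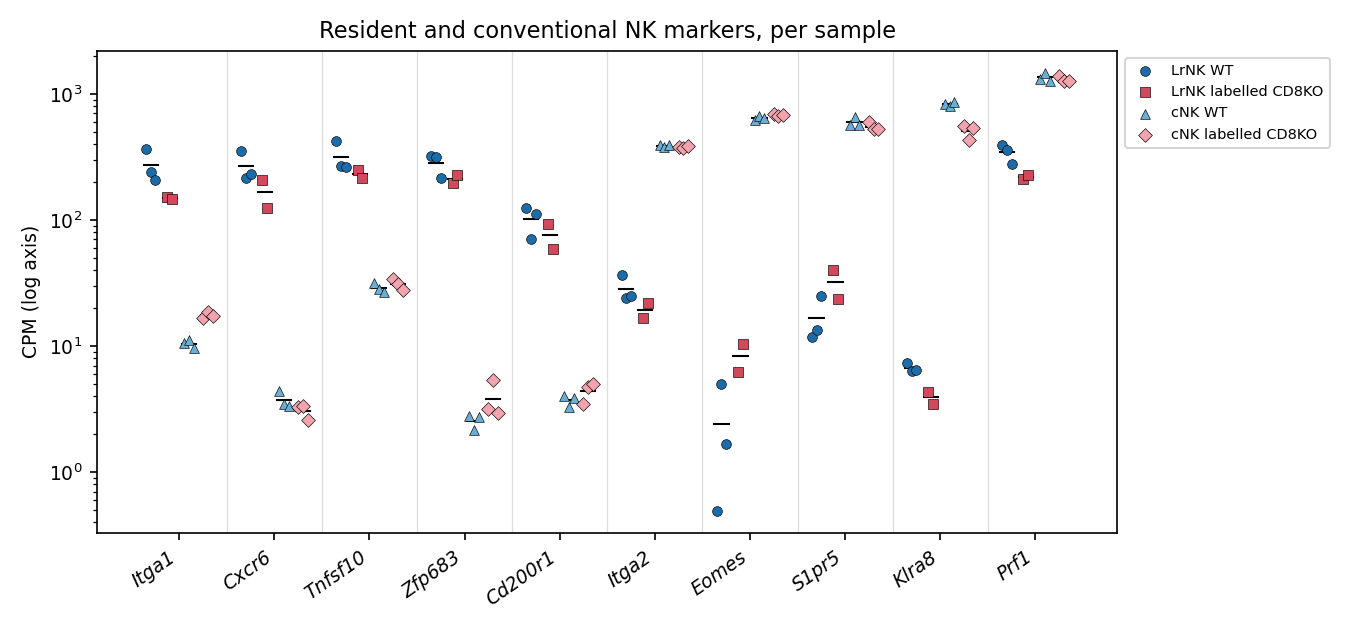
CPM on a log axis for markers of the 2 cell types (x), in each of the 11 samples, with LrNK WT as circles, LrNK labelled CD8KO as squares, cNK WT as triangles, cNK labelled CD8KO as diamonds and group means as black lines. Itga1, Cxcr6 and Tnfsf10 are high in LrNK, and Eomes, Itga2 and S1pr5 in cNK, under both labels.

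Was the contrast of cell types kept in the samples labelled CD8KO? Residence and circulation genes stayed apart. Itga1 (3.08) and Cxcr6 (5.76) remained higher in LrNK, and Eomes (−6.35) and Klra8 (−7.02) lower. Gzma was clearly lower in LrNK (−2.37 ± 0.18, edgeR adjusted p = 1.19e-05), compared with −0.51 between the WT groups. Gzmb was higher in LrNK here too (1.17, edgeR adjusted p = 0.00166). Cd27 passed as lower here (−0.67, edgeR adjusted p = 0.0363), but a difference of its contrast by label was not called (−0.24, edgeR adjusted p = 0.959). The test of that difference recovered 20.5 percent of 2-fold changes in simulated data, so a small difference could not be excluded. Cd8a was lower too (−1.03 ± 0.14, edgeR adjusted p = 0.000549).

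Between the groups labelled CD8KO, 2007 genes were higher and 1482 lower in LrNK, and 57.2 percent separated fully against 20 percent by chance. The largest were Cxcl2 (at least 16730-fold against a floor of 3 counts), Arhgef37 (at least 1954-fold), Ldlrad3 (at least 1479-fold), Alb (at least 1368-fold) and F13a1 (8763-fold, 95 percent counting interval 2426 to 72360). The largest falls were Clip4 (at least 619.7-fold), Rhpn1 (1309-fold, interval 362.3 to 10810), Dpysl5 (510.4-fold, interval 141.3 to 4215), Klhl30 (−8.98 ± 0.66) and Cma1 (−8.74 ± 1.05). Of the lists 28 passed camera and 13 with an estimated correlation. With only these groups fitted, 2735 genes were higher and 2069 lower, 26 lists passed camera and 28 fry, but 0 passed with an estimated correlation (lowest adjusted p = 0.113). Liver-resident genes rose (26 of 28, 1 fell, median 3.06, camera adjusted p = 2.90e-57) and conventional genes fell (20 of 28, 1 rose, median −3.08, 3.04e-39). Activating receptors, which had not passed between the WT groups, were lower (10 fell, 3 rose, median −0.78, camera adjusted p = 0.000228, and adjusted p = 0.0421 with an estimated correlation, but 0.179 so with only these groups). The cytotoxic list did not pass (0.572), and neither did oxidative phosphorylation (0.396) or ribosomal proteins (0.0682). Interferon-stimulated genes rose in 20 of 25 (median 1.60, camera adjusted p = 1.05e-12, but adjusted p = 0.0866 with an estimated correlation), beside neutrophil and monocyte genes (11 rose, median 5.39, 1.62e-17, then 0.00425) and B-cell genes (4.79e-06, then 0.0866).

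Were genes near Cd8a over-represented, as DNA carried along with a targeted allele would give? In the 4-group model, 2 of 273 tested genes within 20 Mb were called in LrNK, beside 134 of 18942 elsewhere (Fisher exact p = 0.720), and none near or elsewhere in cNK once Cd8a itself was left out (Fisher exact p = 1). With cNK fitted alone, 10 of 228 near genes were called (4.39 percent) beside 206 of 16371 elsewhere (1.26 percent, odds ratio 3.60, Fisher exact p = 0.000826). Gm44174 and Gm44175 were among the 10. Genes far apart by label in both cell types were sought among those called with cNK fitted alone, with the groups fully separated, an average log2 CPM of at least 0 and a change of at least 4-fold, Xist and Tsix left out. Of 12 such genes, 9 also differed at least 2-fold in the same direction in LrNK with full separation. Thbs1 and Dab2, higher in every sample labelled CD8KO than in any WT sample of the same cell type, had too few counts in cNK to be tested in that fit. The 9 genes were Apool and Mid1 on chromosome X, Pde1c, Cd8a, Gm44174 and Gm44175 (both directly beside Cd8a) on chromosome 6, Hspa1a and Hspa1b on chromosome 17, and Mid1-ps1, annotated on chromosome Y. Reads of Mid1-ps1 may be shared with Mid1.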

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

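The results named here first were raised because the label's effect differed between LrNK and cNK, by a rule fixed in advance, and the tests of explanations were chosen after the results were seen, except the regroupings of samples. Genes with a different effect (LrNK minus cNK, log2) were Htra3 (−3.162), Cd8a (−6.245), Klri2 (−1.080), Klra5 (−2.076), Klra9 (−1.693), Cd3g (−2.282), Gzma (−1.861) and Bach1 (1.481). Lists with a different effect (camera adjusted p) were the liver-resident signature (3.08e-06), cytotoxic granule genes (1.753e-08), activating receptors (3.54e-10), inhibitory receptors (0.0006994), Ly49 receptors (5.545e-05), interferon-stimulated genes (8.574e-07), oxidative phosphorylation (7.868e-05), ribosomal proteins (0.0001045), class I presentation (0.007165), T cells (0.02113), B cells (2.156e-06) and plasma cells (0.007841). Only activating and Ly49 receptors, 2 of the 12, also passed with an estimated correlation.

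NK receptor and cytotoxic genes were lower in LrNK labelled CD8KO (median of 51 list members −0.42 ± 0.07 by bootstrap over genes, not samples). Their 3 lists were picked after they were seen to be lower. A lower share of NK cells in the sorted population would lower all NK genes alike. Changes of 19 granzyme, perforin, NKp46 and NK lectin genes ranged from −2.14 to 1.22 around a mean of −0.90. That is more than their errors allow (chi-square 104.4 on 18 degrees of freedom, p = 3.415e-14). The chi-square takes these genes as independent and as barely expressed by other cells, which was not checked. Under those assumptions it argues against a lower share of NK cells as the whole cause, but not as a part. It was first run on 45 list members, with the same outcome, and then narrowed to genes of NK cells. Values with detection set as a term argue against libraries with few detected genes as the whole cause, in the 4-group model only. With that term 1802 genes moved by more than 1 log2 unit, while the median stayed at −0.44 ± 0.06. Of the members 20 were then called lower and 3 higher, against 9 and 0 without it. That model was too lenient for LrNK, and no list passed fry or an estimated correlation with LrNK fitted alone. Medians within the sets, −0.32 and −0.45, were tested first and dropped because 1 sample stood in an arm. Sex composition could not be told apart from the label within LrNK. Male RNA was 68.7 to 73.2 percent of cNK WT in LrNK WT, against 39 and 47.5 percent in LrNK labelled CD8KO. Because Xist was at most 1.90 CPM in LrNK WT, these percentages are levels relative to cNK WT and not shares of male cells. A covariate built on them rests mostly on cNK samples. With that covariate the median was −0.39 ± 0.07 and 13 lists were called against 14, but the lower genes went from 34 to 7, as the median size of the 138 changes called went from 1.39 to 1.37 and their median error from 0.205 to 0.241, a loss that a covariate tied to the label brings whatever the cause.

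Of 12 genes called at least 4-fold apart with cNK fitted alone (groups fully separated, average log2 CPM of at least 0, Xist and Tsix left out), 9 were alike in LrNK. DNA around the Cd8a locus that came with the targeted allele may account for some of the 4 within 20 Mb. These were Cd8a itself, Gm44174 and Gm44175 directly beside it, and Pde1c at 15.1 Mb. Near genes were called more often with cNK fitted alone (Fisher exact p = 0.0008264), a fit chosen for this test after the data were seen. Gm44174 and Gm44175 were among its 10 near calls. The 4-group fit gave no excess (Fisher exact p = 0.72 in LrNK, no near call in cNK). The other 5 of the 9 lie farther away, which DNA around the locus would not account for. Sex composition was left open for the set. In 8 of the 9 the 3 cNK samples labelled CD8KO spanned under 50 percent of the difference both in CPM and in log2 CPM, but in Mid1-ps1 they did not. Male RNA in these samples was 92.6, 51.3 and 2.39 percent of cNK WT. Mid1-ps1, annotated on chromosome Y, had 1.60, 1.76 and 3.06 CPM in that order, highest where male RNA was lowest. Its level thus went opposite to male RNA over these samples, and whether it shares reads with Mid1 was not tested. Strain background elsewhere in the genome could be a candidate explanation for the far genes, but with 3 chromosomes holding them and no genotypes it could not be tested.

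Heat-shock genes were lower in cNK labelled CD8KO (median of 4 genes −2.19, cNK fitted alone). Less dissociation stress in general was left open: the 22 immediate-early members of the list had a median of only −0.15, but 16 of them were below 0 and 4 were called lower. Sex composition could not be told apart, since 2 of 4 heat-shock genes had cNK CD8KO samples that spanned under 50 percent of the difference on both scales. Both sex tests were first made with the single male-like sample (9 of 9 and 4 of 4 genes), and changed because 1 library excludes nothing, and then on the log2 scale alone.

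Regrouping the cNK samples in all 10 ways called 1 gene for the real groups and at most 0 for any other in the 4-group model, and 218 for the real groups and at most 1 for any other with cNK fitted alone. Regrouping LrNK WT and cNK WT called 4878 for the real groups and at most 0 for any other. In each case 1 split, the real one, reached the real count, and 10 splits are too few for a share under 0.05.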

How the results depend on the processing

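All values are numbers of genes higher, then lower, unless stated, and the cause was not tested unless stated. No tool or covariate was preferred after the data were seen. Alternatives not run were other annotations, realignment, transcript-level counts and models with unequal spread other than voom's sample weights.

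LrNK labelled CD8KO against WT (104 and 34) moved to 184 higher with no expression filter and 55 lower with CPM of at least 1 in at least 3 libraries, to 0 and 0 with only the groups compared, 774 and 379 with DESeq2, 7 and 5 with voom, and 3 and 8 at adjusted p under 0.01. Chosen after the data were seen, all 13 libraries counted separately gave 512 and 316 (repeats then count as samples), detection set as a term 887 and 303, leaving out the few-detected libraries 2390 and 1245 (LrNK spread was then taken from cNK), and male RNA share as a covariate 3 and 7. Leaving out 1 sample or library at a time gave 5 to 1105 higher and 8 to 420 lower.

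cNK labelled CD8KO against WT (1 and 0) gave 2 and 3 with no filter, 83 and 135 with only the groups compared (the wide LrNK spread is then absent), 9 and 11 with DESeq2, 94 and 99 with voom, 70 and 95 without the few-detected libraries, and 1 lower with all 13 libraries. Leaving out 1 at a time gave 1 to 2 higher and 0 to 1 lower.

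LrNK against cNK in WT (2300 and 2578) gave 1617 lower with only the groups compared, 1340 and 1173 at adjusted p under 0.01, 5532 and 6049 without the few-detected libraries, 1488 and 1416 with male RNA share, and 1405 to 2763 higher and 1531 to 4733 lower with 1 left out. For CD8KO (2007 and 1482) the values were 1257 and 726 at adjusted p under 0.01, 2439 lower with all 13 libraries, 2360 lower with detection set as a term, 5614 and 5402 without the few-detected libraries, and 1302 to 2784 higher and 988 to 2503 lower with 1 left out.

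The difference between cell types (1 and 7) gave 5 higher with no filter, 3 higher with the CPM filter, 2 higher with robust quasi-likelihood, 208 and 129 with DESeq2, 40 and 28 with all 13 libraries, 256 and 71 with detection set as a term, 1904 and 962 without the few-detected libraries, 4 lower with male RNA share, 4 lower at adjusted p under 0.01, and 1 to 569 higher and 4 to 155 lower with 1 left out.

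Pairing by number was run as a replicate block: 11 and 10 for LrNK by label, 1 and 1 for cNK by label, 1983 and 2230 and then 1710 and 1329 for the cell types, and 1 and 5 for the difference. Residuals of samples with the same number correlated with a median r of 0.005 (15 pairs, −0.101 to 0.492) and those with different numbers with −0.002 (30 pairs, −0.492 to 0.197), but the same-number pairs of LrNK WT with LrNK labelled CD8KO gave 0.299 and 0.492. Both pairs also share a detection set, so pairing in LrNK was left open.

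Lists called fell from 14 to 3 for LrNK by label with an estimated correlation (25 with fry, mixed), from 11 to 0 for cNK with an estimated correlation and with both forms of fry (0 and 0), and 7 without the few-detected libraries. For LrNK against cNK they fell to 11 (WT) and 13 (CD8KO) with an estimated correlation, and for the difference to 2, with 3 by directional fry.

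Reversed in direction were the sex-linked list in cNK with male RNA share (adjusted p = 0.0001802 by camera; the covariate is built from members of that list), the cytotoxic list of LrNK WT against cNK WT without the few-detected libraries (adjusted p = 0.7421), and Tbx21 of LrNK against cNK, to 0.66 (WT, detection set as a term), 0.52 (WT) and 0.43 (CD8KO) without the few-detected libraries. The Kupffer list in LrNK by label reversed in 1 of the leave-out fits, with adjusted p from 0.000472 to 0.9563 over them. The Fisher exact p near Cd8a in cNK went from 1 to 0.000675 without the few-detected libraries, 0.0008264 with only the groups compared and 0.03805 with that fit and 10 Mb.

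Of 140 calls of single genes named here, none reversed. DESeq2 kept 140, RLE 139, voom 104, replicate block 111, detection set as a term 136 and male RNA share 98, and only the groups compared 88 of 132. Kept under every setting were 0 of 41 in LrNK by label, 1 of 1 in cNK, 56 of 62 and 26 of 28 between cell types, and 4 of 8 for the difference.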

Other observations

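The tests named here were chosen after the results were seen. In LrNK labelled CD8KO the cytotoxic and receptor lists were lower in the 4-group model. The median of their 51 members was −0.42, and −0.44 with detection set as a term. In that model this argues against libraries with few detected genes as the whole cause. A change within LrNK cells might account for the lower lists and is a hypothesis only. B-cell, plasma-cell, neutrophil and monocyte, and Kupffer-cell lists were higher in the same libraries (medians 3.04, 1.82, 1.59 and 0.56) at the preset correlation but not with an estimated one. Summed CPM of all but the plasma-cell list overlapped between the labels. A lower share of NK cells was left open as part of the cause. With male RNA share as a covariate the median of the 51 members was −0.39 and 13 lists were called against 14. That could not decide on a sex effect, because the covariate was tied to the label in LrNK and rested mostly on cNK samples. A sex effect was left open. With the covariate the lower genes went from 34 to 7 and the higher from 104 to 3, which a covariate tied to the label costs whatever the cause. LrNK samples of known purity from animals of 1 sex would test the hypothesis of a change within LrNK cells.

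Cd3g, which LrNK WT carried far above cNK, fell in LrNK labelled CD8KO together with Gzma and the Ly49 genes. It could reflect fewer contaminating T cells or a program of NK cells. Changes of 19 NK genes differed by more than their errors allow (p = 3.415e-14 by chi-square). That takes the genes as independent and as barely expressed by other cells, which was not checked. Cd3g was not part of that test. The T-cell list itself did not pass in that comparison (camera adjusted p = 0.514).

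Further work on these data would need reads over the exons of Cd8a to show what the CD8KO allele transcribes, the sex and animal of each sample, and LrNK libraries with similar numbers of detected genes.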
